A study of Mus musculus with 82 samples.

How the data were processed

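RNA was measured in the extended amygdala of female C57BL/6J mice, 2 months old, that drank under 24 h two-bottle choice (20% ethanol against water) for 30 days, or drank water only. Per the labels, synaptoneurosomes (SN) were made by pressing a homogenate through filters of 100 µm and then 5 µm and spinning it at 14000 g for 20 min. A share of 10% of the same homogenate was kept as total homogenate (TH). Messenger RNA was hybridized to Illumina Mouse WG-6 v2.0 BeadChips (42 arrays from 21 mice, 8 with alcohol and 13 controls), and microRNA (miRNA) to Affymetrix miRNA 3.0 arrays (40 arrays from 20 mice, 8 with alcohol and 12 controls). Per the labels, samples of both fractions and both groups shared each BeadChip and were assigned at random. The TH mRNA arrays of controls 11 and 12 were titled as outliers by the authors and are not in the mRNA tables. That leaves 40 mRNA arrays, 11 control pairs and 19 mice with both fractions. Control 4 has no miRNA array.

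Per the file headers, the mRNA signal tables hold average bead signals, an intensity on a linear scale, with a detection p-value per probe and array. They hold all 45281 probes, were not normalized between arrays and were not background subtracted. The values of the normalized mRNA tables deposited by the authors are on a log2-like scale. Their distributions are nearly identical between arrays, so they are quantile-normalized in effect, and each of the 3 tables was normalized on its own. Against the log2 of the signals the scale is compressed at low signal, with a ratio of SDs of 0.43 to 0.49 among the probes of lowest level and 0.90 among those of highest level, so changes of weakly expressed genes are understated. The submitters' processing notes name lumi but not which of its transforms was used. The miRNA values are log2 values after RMA per the submitters' processing notes, which also name oligo and limma. Versions of the authors' tools are not given in the sources used here.

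From the files it was found that the authors' normalized tables keep probes with a detection p-value under 0.05 on at least 80% of the arrays of each. That left 17820 probes for SN against TH, 17514 for SN and 18318 for TH, with 12623, 12432 and 12916 genes. Old array symbols were updated through a table of gene names of GRCm38.p6, used for names alone. Of 13241, 13033 and 13555 symbols, 10533, 10424 and 10724 were current or could be updated, and the others were used as the array gives them. The miRNA file holds 1111 mouse mature probe sets, 332 of them star strands, and 0 hairpins. miRNA names are those of the array. No further filter was applied. The number of arrays limits the precision.

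Each comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjustment over all probes of the comparison, adjusted p under 0.05), with the package data.table (version 1.17.8) for reading the files. SN against TH was tested in control mice with the mouse as a block, and alcohol against control in each fraction without a block. Adjusted p-values are those of limma unless another test is named. The difference between the alcohol effects in SN and in TH was tested on each mouse's SN minus TH difference. For mRNA it used log2 signals that were quantile-normalized jointly over both fractions, for the 17265 probes kept in both normalized alcohol tables. The plan had named the probes of both signal tables, but these hold every probe of the array, expressed or not. Agreement of the alcohol effects between fractions was set against 100 joint relabellings of the mice. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

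Groups of genes were tested with camera of limma at a preset correlation of 0.01, with 1 probe per gene (the highest mean level) and adjustment over the lists of a comparison. Camera asks whether a list moved relative to the other genes measured. Each call was repeated with an estimated correlation and with fry, which tests whether the members move, on balance, one way. The 27 gene lists were dendritically localised mRNAs, postsynaptic density, presynaptic vesicle and release, GABA signalling, glutamate receptors, amygdala neuropeptides and receptors, ethanol-sensitive ion channels with adenosine signalling, and markers of astrocytes, microglia, oligodendrocytes, oligodendrocyte precursors, endothelial and mural cells and choroid plexus. Further lists were markers of striatal neurons, of cortical and hippocampal neurons and of thalamic and hypothalamic neurons, nuclear-retained noncoding RNAs, ribosomal proteins, oxidative phosphorylation, splicing factors, immediate early genes, glucocorticoid-responsive genes, heat shock and unfolded protein response, innate immunity, ethanol metabolism, cholesterol biosynthesis and translation factors. The 11 miRNA lists were the let-7 family, neuron-enriched miRNAs, the cluster from miR-379 to miR-410, miRNAs reported in dendrites or synaptic fractions, astrocyte and oligodendrocyte miRNAs, blood, immune and endothelial miRNAs, choroid plexus miRNAs, the families of miR-29 and miR-30, the cluster of miR-17 and miR-92 with its paralogs, the families of miR-15, miR-16, miR-23, miR-24 and miR-27, and miRNAs named in earlier alcohol studies. Star strands do not match a list.

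Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Genes are named by that rule. For mRNA these are the 10 largest rises and the 10 largest falls among probes that pass, 1 probe per gene, without unnamed transcripts. Where fewer than 10 pass, they are those that pass and the 6 smallest unadjusted p-values in each direction, given as not passing. For miRNA the numbers are 8 and 4. Up to 4 members of each list that passes and up to 2 of each other list are added, with a fixed set for each comparison (Camk2a, Ddn, Dlg4, Syp, Gfap, Aif1, Mbp, Malat1 and Meg3 for the fractions; Crh, Npy, Penk, Pdyn, Gabra2, Fkbp5, Gfap, Mbp, B2m and Ttr for alcohol; for miRNA miR-124, miR-9, miR-134, miR-138, miR-219, miR-142 and miR-451, and miR-9, miR-155, miR-124, let-7b, miR-206 and miR-411). The text gives the ones of these that carry a comparison. Exclusions by name were applied to the updated symbols.

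Pairing by mouse was checked on the values. After removal of group means, the SN and TH mRNA profiles of 1 mouse correlated across probes at a median r of 0.39 (0.08 to 0.67 over 19 mice), with 14 of 19 closest to their own partner, against a median of -0.01 for other mice. On the miRNA arrays the median r was 0.06 (-0.20 to 0.25), with 4 of 20 closest to their own partner, so that pairing rests on the study design and not on the values. Alcohol and control mice of the same number were not alike (median r 0.01 in SN and -0.10 in TH) and were not paired. The fits were tested on simulated data with 200 changed probes, assuming independent noise. At a log2 change of 0.50 they recovered 100% for mRNA SN against TH, 97.0% and 94.0% for alcohol in SN and TH, and 83.6% for the difference of the effects. For miRNA the shares were 79.1%, 85.1%, 67.2% and 41.8%. At 0.25 the shares were 88.1%, 70.1%, 85.1% and 29.9% for mRNA and 26.9%, 25.4%, 25.4% and 4.48% for miRNA, in the same order.

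Alternatives covered the values (log2 and quantile-normalized signals, arrays centred on their medians), filters by level or detection p under 0.01, 1 probe per gene, trend and robust variances, array weights, an unmoderated test per probe, blocks, mice with both fractions, and leaving out each mouse. Added after the data were seen were leaving out controls 12 and 13 and testing the lists under other scalings. The TH mRNA arrays of controls 11 and 12 were not used here. The miRNA arrays of these mice were used, and an alternative left these mice out. A block for the BeadChip could not be fitted, since the column names give no chip.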

Results

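Gene expression was measured in 82 samples of extended amygdala, the forebrain region that links stress, reward and alcohol drinking. Each mouse gave a synaptoneurosome fraction (SN), a filtered preparation enriched in pinched-off synaptic endings with the processes around them, and a paired total homogenate (TH). The mRNA arrays used here were 13 control and 8 alcohol SN, and 11 control and 8 alcohol TH. The miRNA arrays were 12 control and 8 alcohol in each fraction. SN arrays of controls detected 16878 ± 462 probes (SD, n = 13) at a detection p under 0.01, and SN arrays of alcohol mice 16336 ± 429 (SD, n = 8), a difference of -542 (exact permutation test, two-sided, p = 0.0144, adjusted over both fractions 0.0289). TH arrays detected 17303 ± 340 in controls (n = 11) and 17509 ± 256 in alcohol mice (n = 8; exact permutation p = 0.167). Median signals were 113.7 ± 4.69 and 110.7 ± 4.04 in SN of controls and alcohol mice, and 118.8 ± 2.37 and 119.1 ± 3.92 in TH (SD).

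The first comparison asked which mRNAs SN hold more or less of than the homogenate they came from, in 11 control mice. Genes of brain vessels fell most. Ly6a, an endothelial surface antigen, fell by 2.00 on the log2 scale (SE 0.05, adjusted p 3.16e-10), and Cxcl12, a chemokine made by vessel cells, fell by 1.96 (SE 0.04, adjusted p 6.44e-11). Cldn5, which seals the junctions of the blood-brain barrier, fell by 1.80 (SE 0.06), the VEGF receptor gene Flt1 by 1.65 (SE 0.05) and Ly6c1 by 1.41 (SE 0.05), each lower in SN in all 11 pairs. Esam, an endothelial adhesion molecule, fell by 1.38 (SE 0.05), smooth-muscle actin Acta2 by 1.38 (SE 0.15), Igfbp7 by 1.36 (SE 0.06) and Itm2a by 1.21 (SE 0.04). The nuclear RNA Xist, which silences an X chromosome, fell by 1.06 (SE 0.12). Of 17 endothelial and mural markers, 15 fell, 0 rose and 2 did not pass, with a median of -0.84 (camera adjusted p 4.89e-13; 15 fell when adjusted over the list alone). This call held with an estimated correlation (adjusted p 0.0286).

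Astrocyte markers were higher in SN as a group, and the largest single rises were of several kinds. Ppp1r3c, which directs glycogen synthesis, rose by 1.37 (SE 0.06, adjusted p 2.82e-08), and the fatty acid desaturase Scd1 by 1.25 (SE 0.07). The myelin-related genes Bcas1 and Mobp rose by 1.23 (SE 0.09) and 1.06 (SE 0.15), although the 5 probes of Mobp ranged from -0.06 to 1.06. The mitochondrial transcripts mt-Co2, a subunit of cytochrome oxidase, and ND4L, of complex I, rose by 1.05 (SE 0.08) and 1.36 (SE 0.10). Plekhb1 rose by 1.16 (SE 0.07), Tns3 by 1.03 (SE 0.05) and Gfap, the astrocyte intermediate filament, by 1.05 (SE 0.08). All 25 astrocyte markers rose, 25 also when adjusted over the list alone, with a median of 0.42 (camera adjusted p 1.08e-14; adjusted p = 0.0286 with an estimated correlation). Among them were Ndrg2 at 1.01 (SE 0.05), the glycolytic enzyme Aldoc at 0.97 (SE 0.05), the acyl-CoA synthetase Acsbg1 at 0.92 (SE 0.06) and the glutamate transporter Slc1a2 at 0.66 (SE 0.05). Of 23 microglia markers 10 rose, 1 fell and 12 did not pass (median 0.11, camera adjusted p 0.0025, lost at adjusted p = 0.483 with an estimated correlation; 10 and 1 when adjusted over the list alone). Aif1, a microglial calcium-binding protein, rose by 0.45 (SE 0.07) and the growth factor receptor Csf1r by 0.30 (SE 0.03). Oligodendrocyte markers went both ways, with 5 rises, 7 falls and 6 not passing of 18. Their median was -0.09 and their mean 0.09 (camera adjusted p 0.974; 6 and 8 when adjusted over the list alone). Mbp, the major myelin protein whose mRNA travels into processes, rose by 0.80 (SE 0.08), and Olig1, a lineage transcription factor, by 0.50.

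Several postsynaptic mRNAs rose. Of 24 mRNAs known to be carried into dendrites, 14 rose, 1 fell and 9 did not pass (median 0.30, camera adjusted p 0.0012; 14 and 2 when adjusted over the list alone), a call that was lost at adjusted p = 0.141 with an estimated correlation. The kinesin motor genes Kif5a and Kif5c rose by 0.85 (SE 0.06) and 0.60 (SE 0.04), and Ddn, a dendritic actin-associated protein, by 0.61 (SE 0.06). Of 33 genes of the postsynaptic density 14 rose, 1 fell and 18 did not pass (median 0.05, camera adjusted p 0.0064; 14 and 1 when adjusted over the list alone; adjusted p = 0.478 with an estimated correlation). Camk2a, the kinase of synaptic plasticity, rose by 0.63 (SE 0.09), the scaffold Dlg4 by 0.44 (SE 0.07), Homer2 by 0.65 (SE 0.06) and Psd3 by 0.34 (SE 0.04). Of 25 presynaptic genes 2 rose, 9 fell and 14 did not pass (median -0.10, camera adjusted p 0.0679). Sncb, a presynaptic protein gene, fell by 0.43, and the vesicle protein gene Syp stood at -0.14 (SE 0.07, adjusted p 0.141). GABA signalling had 4 rises and 3 falls of 16 (median -0.04, mean 0.04, camera adjusted p 0.865), with rises of 0.60 in Abat, which breaks GABA down, and of 0.43 in the glial GABA transporter Slc6a11. Glutamate receptors had 3 rises and 0 falls of 14 (median 0.04, camera adjusted p 0.380), with Grik5 at 0.35 and Grm5 at 0.29. Adjusted over the list alone, glutamate receptors had 2 rises, and the counts of presynaptic and GABA genes were as given.

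Neuropeptide mRNAs were lower in SN. Of 22 neuropeptide and receptor genes 13 fell, 1 rose and 8 did not pass (median -0.21, camera adjusted p 0.000157; 15 and 1 when adjusted over the list alone; adjusted p = 0.0286 with an estimated correlation). Npy fell by 0.83 (SE 0.05), Cck by 0.78 (SE 0.05), Sst by 0.68 (SE 0.07) and Cartpt by 0.61 (SE 0.08), each encoding a secreted peptide of local neurons. Nuclear-encoded genes of oxidative phosphorylation fell in 36 of 58, rose in 3 and did not pass in 19 (median -0.20, camera adjusted p 2.6e-07; 40 and 4 when adjusted over the list alone). Atp5g1, of ATP synthase, fell by 0.58 (SE 0.06), and Ndufv2, of complex I, by 0.30; this list had adjusted p = 0.478 with an estimated correlation. Ribosomal protein genes rose in 31 of 57, fell in 2 and did not pass in 24 (median 0.15, camera adjusted p 1.27e-05; 33 and 2 when adjusted over the list alone), with Rps3 at 0.48 (SE 0.06) and Rpl22 at 0.30; adjusted p = 0.483 with an estimated correlation. Genes of the heat shock and unfolded protein response fell in 12 of 23 and rose in 0, with 12 also when adjusted over the list alone (median -0.11, camera adjusted p 0.00225; adjusted p = 0.275 with an estimated correlation). Their transcription factor Xbp1 fell by 0.49 (SE 0.06). Splicing factors fell in 10 of 26, rose in 1 and did not pass in 15, with 10 and 1 when adjusted over the list alone (median -0.08, camera adjusted p 0.0153; adjusted p = 0.478 with an estimated correlation). Srsf5 fell by 0.55 (SE 0.08). The noncoding RNA Meg3 stood at -0.15 (SE 0.18, adjusted p 0.546), and Malat1 was not among the probes kept.

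In total 7045 of 17820 probes passed in limma (39.5%; 3368 up, 3677 down; 5612 genes), with a median size of 0.18 and only 13 rises and 19 falls over 2-fold. Of 3790 genes with several probes, 52 had probes called both ways. A gene is given by its probe of highest mean level; other probes of Cxcl12 reached -0.14, of Acta2 -0.10, of Xist -0.19, of Tns3 -0.07 and of Gfap 0.43.

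**Figure D1:**
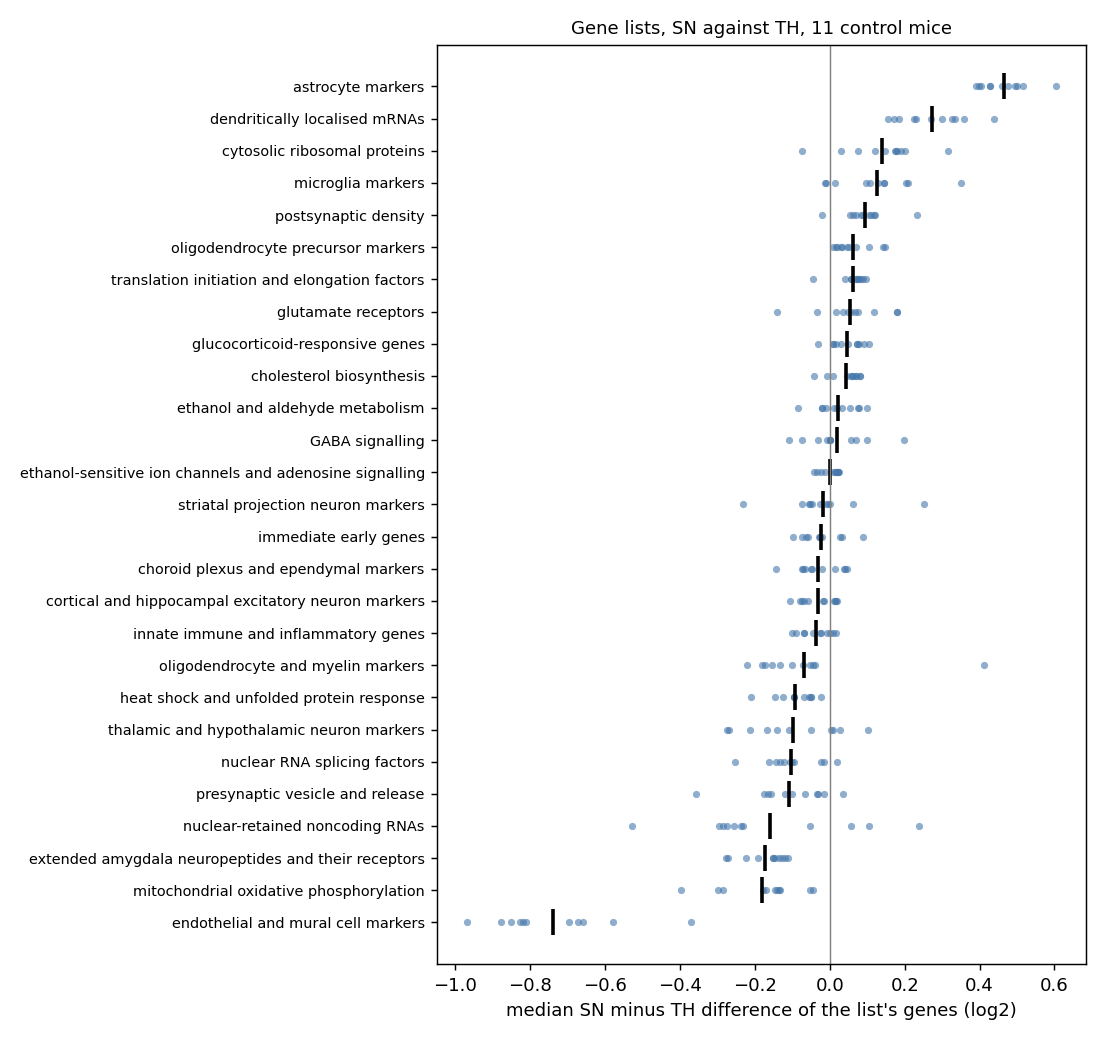
Each point is the median SN minus TH difference (log2, x axis) of a gene list's members in 1 control mouse (11 mice), and the black bar is the mean of the mice. Astrocyte markers averaged 0.46 ± 0.06 (SD) and endothelial and mural markers -0.74 ± 0.17. Oligodendrocyte markers averaged -0.07 ± 0.17, with control 4 at 0.41 and the other mice from -0.22 to -0.04.

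The same question was asked of miRNAs in 12 control pairs. The largest falls included miRNAs of vessel walls. The lymphocyte miRNA miR-150 fell by 3.03 (SE 0.20, adjusted p 3.53e-08), the smooth-muscle miRNAs miR-145 and miR-143 by 2.41 (SE 0.10, adjusted p 1.65e-10) and 2.27 (SE 0.11), and the endothelial miR-126-3p by 2.11 (SE 0.09), the last lower in all 12 pairs. The red-cell miRNA miR-451 stood at 0.04 and did not pass. Next were miR-690 at -1.91 (SE 0.18), miR-5099 at -1.85 (SE 0.27), miR-3473 at -1.62 and miR-5107 at -1.44. In SN miR-3473 averaged 1.32, close to the array medians of 0.82 to 1.00, so the size of its fall is at best a lower bound. Rises were smaller. The largest were miR-652-star at 0.82 (SE 0.17) and miR-9-star, of a neural miRNA gene, at 0.80 (SE 0.12), higher in 12 of 12 pairs. The other strand, miR-9, stood at 0.16 (SE 0.15, adjusted p 0.654) and did not pass. miR-181a-1-star rose by 0.57, miR-92b by 0.53, miR-495 by 0.53, miR-146a by 0.50, miR-376a by 0.48 and the oligodendrocyte miRNA miR-338-5p by 0.46. From the fixed set miR-219-3p rose by 0.42 (adjusted p 0.0256), while miR-219-5p stood at 0.25 without passing. The neuronal miR-124 stood at 0.01 (SE 0.06), and the dendritic miR-134 and miR-138 at 0.12 and -0.06; none of these passed. miR-124 lay at 13.4 in both fractions, near the highest value of the table (13.5), so its difference is no measure of stability.

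No miRNA list passed camera on the values as deposited, while fry passed 5 of 11. Of the 41 members of the cluster from miR-379 to miR-410, 2 rose, 0 fell and the others did not pass (median 0.09). Of 25 miRNAs reported in dendrites 3 rose and 0 fell (median 0.12), and of 14 in the cluster of miR-17 and miR-92 2 rose and 0 fell (median 0.15), with miR-106b at 0.46 and miR-93 at 0.38. Each of these lists had a camera adjusted p of 0.0502, which became 0.0354 after quantile normalization. The families of miR-29 and miR-30 had 1 rise of 8, miR-30b at 0.31 (median 0.18, adjusted p 0.0940). Neuron-enriched miRNAs had 2 rises of 23 (median 0.12, adjusted p 0.0961), miR-383 at 0.29 and miR-212-3p at 0.24, and the let-7 family 0 of 9 (median 0.08, adjusted p 0.275). Choroid plexus miRNAs had 0 calls of 18 (median -0.10, adjusted p 0.0961), among them miR-34c at -0.57 (adjusted p 0.0625). Blood, immune and endothelial miRNAs had 1 rise and 2 falls of 17, with a median of 0.03 against a mean of -0.22 (adjusted p 0.417). Astrocyte and oligodendrocyte miRNAs had 2 rises and 1 fall of 19, with a median of 0.02 and a mean of -0.04 (adjusted p 0.821); the fall was that of miR-143, named above for smooth muscle. The families of miR-15, miR-16, miR-23, miR-24 and miR-27 had 0 calls of 11, with a median of -0.07 and a mean of 0.03 (adjusted p 0.961), and miRNAs of earlier alcohol studies 2 rises of 36 (median 0.05, adjusted p 0.417). Adjusted over the list alone, miRNAs of dendrites had 4 rises, the families of miR-29 and miR-30 had 2, and astrocyte and oligodendrocyte miRNAs 3 with 1 fall; other counts were as given.

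In all, 69 of 1111 probe sets passed in limma (6.21%; 29 up, 40 down), with 18 falls and 0 rises over 2-fold. Without control 2 the count was 42 (14 up, 28 down) and without control 3 it was 43 (11 up, 32 down).

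**Figure D2:**
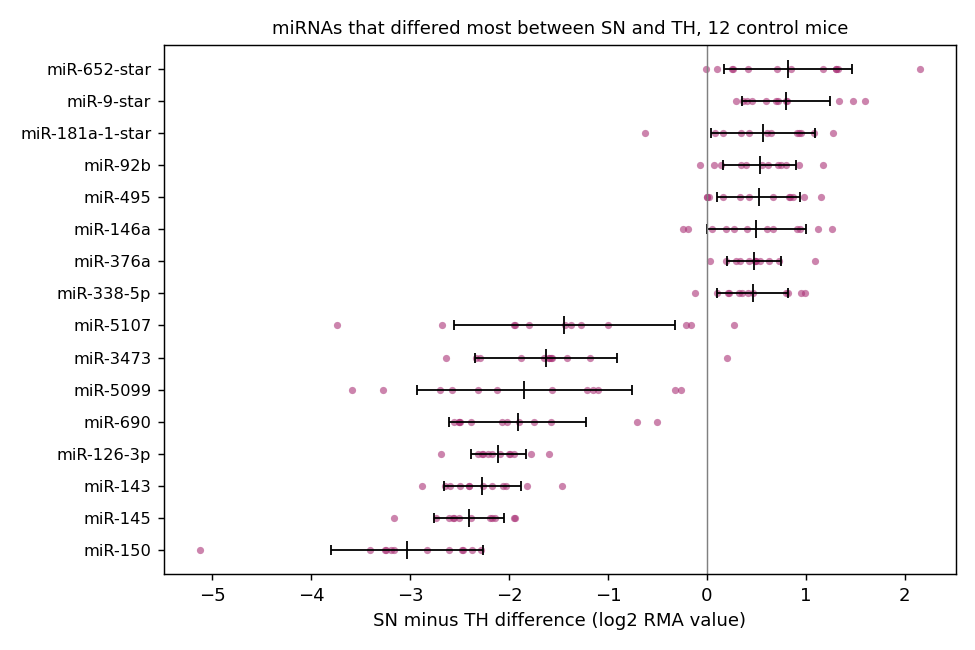
Each point is the SN minus TH difference (log2 RMA value, x axis) of 1 miRNA in 1 control mouse (12 mice), with the mean ± SD in black, for the 8 largest rises and falls. miR-150 averaged -3.03 and miR-652-star 0.82.

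The next comparison asked which mRNAs of SN differed after 30 days of drinking, in 8 alcohol against 13 control mice. No probe passed, so values are given as measured. The smallest p-values among higher probes belonged to Kars, a lysyl-tRNA synthetase, at 0.20 (SE 0.04, adjusted p 0.383), Sfxn5, a mitochondrial carrier, at 0.34 (SE 0.08), Cpped1 at 0.26 and Pabpc4, a poly(A)-binding protein, at 0.16. Both Kars and Sfxn5 lay above the control median in 8 of 8 alcohol mice. Among lower probes they belonged to Ypel3 at -0.17, Cnrip1, which binds the cannabinoid receptor, at -0.20, and the somatostatin receptor Sstr2 at -0.23. Second probes of Kars, Ypel3 and Cnrip1 stood at 0.030, 0.033 and 0.031. The stress and opioid peptide genes Npy, Penk and Pdyn stood at -0.14 (SE 0.08), 0.06 and -0.05, Gfap at 0.23 (SE 0.12), Mbp at 0.04, B2m at 0.12 and the glucocorticoid-induced Fkbp5 at -0.02; Crh and Gabra2 were not among the probes kept. Ttr, the thyroid hormone carrier of the choroid plexus, was 9.52 ± 0.86 (SD, n = 8) in alcohol mice and 11.3 ± 2.10 (n = 13) in controls, a difference of -1.80 (SE 0.75, adjusted p 0.450).

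Gene groups in SN moved by little, and 0 members of any list passed over all probes. Relative to other genes, 13 lists passed camera at the preset correlation, and none of them held with an estimated one. Ribosomal proteins (57 genes, median 0.08, adjusted p 8.43e-06; Rps13 0.32, Rps6 0.32) and oxidative phosphorylation (58 genes, median 0.09, adjusted p 1.96e-05; Sdhc 0.18; another probe of Rps13 stood at -0.047) lay higher at the preset correlation, with adjusted p = 0.473 with an estimated correlation for both. So did markers of astrocytes (25, median 0.11, adjusted p 0.000275; Acsbg1 0.24), with 21 of 25 above 0, and of microglia (23, median 0.08, adjusted p 0.000525; C1qb 0.27, Laptm5 0.25), again with adjusted p = 0.473 with an estimated correlation for both. Ethanol metabolism (15, median 0.08, adjusted p 0.00146) held Aldh2, which clears acetaldehyde, at 0.21 and Adh5 at 0.20 (adjusted p = 0.473 with an estimated correlation). Oligodendrocyte precursor markers (9, median 0.05, adjusted p 0.00358) had 2 members that passed when adjusted over the list alone, Tmem100 at 0.24 and Gpr17 at 0.18 (adjusted p = 0.171 with an estimated correlation). Endothelial markers (17, median 0.02, adjusted p 0.0086) and innate immune genes (22, median 0.03, adjusted p 0.0136) lay higher as well, with adjusted p = 0.473 with an estimated correlation for both. Choroid plexus markers (10, median -0.25, adjusted p 0.00358), glutamate receptors (14, median -0.07, adjusted p 0.0053; Grm5 -0.25, Grm7 -0.14, with another Grm7 probe at 0.032) and presynaptic genes (25, median -0.08, adjusted p 0.00675) lay lower, with adjusted p = 0.473 with an estimated correlation for each. In the presynaptic list Slc17a6 stood at -0.45 and Syt1 at -0.16. Slc17a6 was lower in TH too, at -0.35. Immediate early genes (16, median -0.05, adjusted p 0.0175; Egr1 -0.32) and nuclear-retained noncoding RNAs (9, median -0.23, adjusted p 0.0289; Snhg11 -0.35, Miat -0.32, Kcnq1ot1 -0.30) also lay lower, with adjusted p = 0.473 with an estimated correlation for both. In fry the oligodendrocyte precursor list alone passed, at adjusted p 0.0223. Among splicing factors, a list that did not pass, 1 gene passed when adjusted over the list alone, the spliceosome core gene Prpf8 at -0.21. Median and mean differed in sign for ion channels and for heat shock genes, which did not pass.

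SN of alcohol mice had fewer detected probes, by a difference of -542, and a pair of control SN arrays stood apart; neither was tested against the lists one by one beyond leaving that pair out. SN of controls 12 and 13 differed alike from the mean of the other SN arrays, alcohol mice included (r 0.875 across 17514 probes, which are not independent). Their median deviations from the control medians were 0.86 and 0.71 for nuclear-retained noncoding RNAs and -0.17 and -0.19 for oxidative phosphorylation, and Ttr was 14.7 and 13.7. In limma 0 of 17514 probes passed (smallest adjusted p 0.383), while 1878 had an unadjusted p under 0.05 (1097 up, 781 down), against 876 by chance; an unmoderated test per probe gave 0 and 1859. The unadjusted count was 1157 without controls 12 and 13, and 1240 without alcohol mouse 7. Without controls 12 and 13 the lists of nuclear-retained noncoding RNAs and of immediate early genes no longer passed and striatal markers did (median 0.09, adjusted p 0.0076; adjusted p = 0.615 with an estimated correlation). None of the lists passed there with the estimate, whose smallest adjusted p was 0.126. Striatal markers in SN of alcohol mouse 8 had a median deviation from the controls of 0.68, against -0.22 to 0.23 in the other alcohol mice. Without controls 12 and 13, medians of most lists that still passed were smaller, at 0.038 for oxidative phosphorylation, 0.034 for ethanol metabolism, 0.044 for microglia, -0.041 for presynaptic genes, -0.040 for glutamate receptors and -0.14 for choroid plexus markers. Ribosomal proteins (0.059, camera adjusted p 0.00012) and astrocyte markers (0.085, camera adjusted p 0.00052) shrank less, and endothelial markers stayed at 0.02.

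In TH the same question was asked of 8 alcohol and 11 control mice, and again 0 probes passed. Zfand3 stood at 0.16 (SE 0.03), Nbl1, a secreted BMP antagonist, at 0.18 (SE 0.05), Tgm2, a transglutaminase, at 0.18 and the bicarbonate transporter Slc4a8 at 0.16. Brinp3 stood at -0.18 (SE 0.04), the actin-nucleating Arpc3 at -0.20 (SE 0.05), Wapl, which releases cohesin, at -0.17 (another probe 0.0088) and the cell death gene Bax at -0.14. Ttr was 10.4 ± 1.01 (SD, n = 8) and 11.7 ± 2.06 (n = 11), a difference of -1.28 (SE 0.75). Npy, Penk and Pdyn stood at -0.08, 0.00 and -0.03, Gfap at 0.05, Mbp at -0.01, B2m at 0.02 and Fkbp5 at -0.01.

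Among gene groups in TH, 9 lists passed camera at the preset correlation, with 0 members passing over all probes. Markers of endothelial and mural cells (22, median 0.04, camera adjusted p 6.01e-05; Vwf 0.25, Flt1 0.24), of striatal neurons (13, median 0.09, adjusted p 0.000214; Gng7 0.22, Pde1b 0.11) and of astrocytes (24, median 0.06, adjusted p 0.000647; Gja1 0.11) lay higher, with adjusted p = 0.412 with an estimated correlation for each. Postsynaptic (33, median 0.03, adjusted p 0.00446; Grm5 0.22, Homer2 0.17), dendritic (24, median 0.03, adjusted p 0.017; Ddn 0.19) and presynaptic genes (26, median 0.03, adjusted p 0.0231; Cplx1 0.11) did too, with adjusted p = 0.412 with an estimated correlation for each. Oxidative phosphorylation (58, median -0.03, adjusted p 0.00111; Atp5j2 -0.14), choroid plexus markers (10, median -0.23, adjusted p 0.00168; Ecrg4 -0.46, Prlr -0.30) and ribosomal proteins (57, median -0.03, adjusted p 0.0111; Rps16 -0.11) lay lower. None held: adjusted p = 0.556 with an estimated correlation for ribosomal proteins and adjusted p = 0.412 with an estimated correlation for the other lists, and fry called 0. Adjusted over the list alone, 0 members of any list passed. Slc17a6 went against the direction of its presynaptic list, at -0.35 (SE 0.20). Striatal markers of alcohol mouse 8 stood apart in TH, with a median deviation from the controls of 0.58, against -0.19 to 0.33 in the other alcohol mice. Single mice were not left out of the list tests, so the weight of this mouse was not tested. Median and mean differed in sign for GABA signalling, glutamate receptors, microglia, oligodendrocytes and heat shock genes, which did not pass. In limma 0 of 18318 probes passed (smallest adjusted p 0.999), 571 had an unadjusted p under 0.05 (283 up, 288 down; 916 by chance), and an unmoderated test per probe gave 0 and 608. With mice of equal number as a block, which keeps only the numbers present in both groups, the unadjusted count was 1060.

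**Figure D3:**
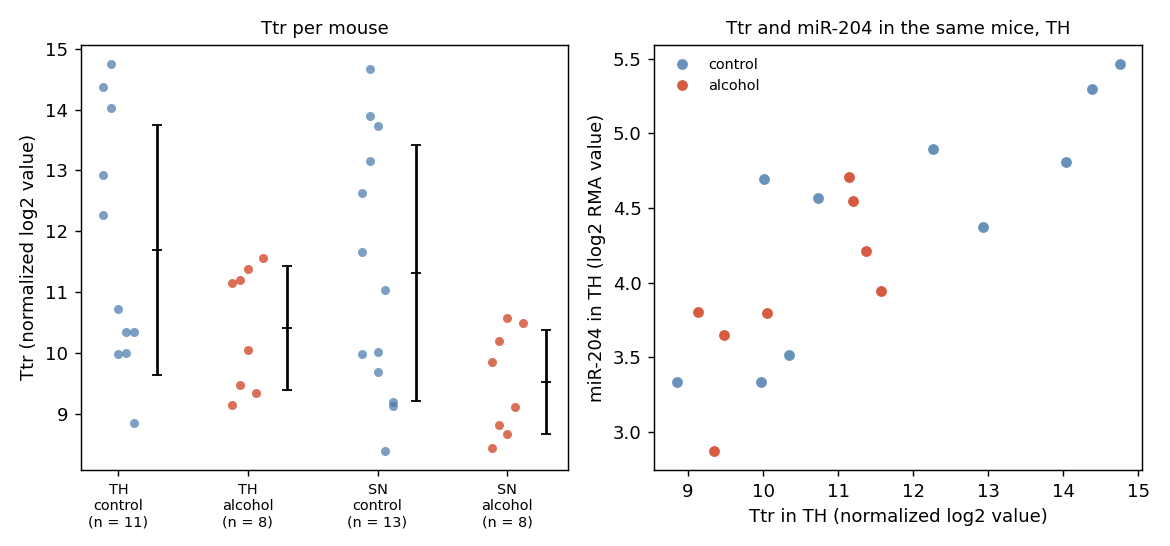
Left, Ttr (normalized log2 value, y axis) in each mouse by fraction and treatment, with the mean ± SD in black; alcohol mice averaged 9.52 in SN and 10.4 in TH, and controls 11.3 and 11.7. Right, miR-204 (log2 RMA value) against Ttr in TH, 1 point per mouse (18 mice); alcohol mice are red and controls blue.

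Whether the alcohol effect differed between fractions was tested on the SN minus TH difference of 8 alcohol and 11 control mice. No single gene passed. Among these mice the number of detected probes differed between the groups by -507 in SN and by 206 in TH. The difference of effects was 0.42 (SE 0.08) for Atp5g2, a subunit of ATP synthase, 0.60 (SE 0.13) for Metrn, a glial secreted factor, 0.33 (SE 0.07) for Arpc3 and 0.31 for Kars. It was -0.48 (SE 0.10) for Rapgefl1, -0.25 for Gramd1b, -0.21 for Gnpda1 (another probe 0.028) and -0.33 for the corepressor Rcor1 (another probe 0.031). At the preset correlation 8 lists passed camera, and none held with an estimated one. Ribosomal proteins (57, median 0.11, camera adjusted p 5.73e-10) lay above 0 in 52 of 57, with Rpl18 at 0.33 (SE 0.09) and Rps16 at 0.28 (SE 0.08), the 2 that passed when adjusted over the list alone (adjusted p = 0.363 with an estimated correlation). Oxidative phosphorylation (58, median 0.11, adjusted p 1.12e-08) lay above 0 in 50 of 58, with 1 gene, Ndufa7 at 0.26 (SE 0.07), passing when adjusted over the list alone (adjusted p = 0.363 with an estimated correlation). Microglia markers (23, median 0.11, adjusted p 0.000769) held the complement genes C1qa at 0.27, C1qb at 0.27 and C1qc at 0.26, and ethanol metabolism (15, median 0.10, adjusted p 0.0045) held Aldh2 at 0.29, with adjusted p = 0.363 with an estimated correlation for both. Presynaptic genes (25, median -0.13, adjusted p 3.48e-05) lay above 0 in 2 of 25, with Cplx2 at -0.37 and Syn2 at -0.32, another of whose probes stood at 0.063 (adjusted p = 0.363 with an estimated correlation). Postsynaptic genes (33, median -0.10, adjusted p 0.00547) had 2 that passed when adjusted over the list alone, Grm5 at -0.49 (SE 0.12) and Lrrtm1 at -0.31 (adjusted p = 0.363 with an estimated correlation). Glutamate receptors (14, median -0.12, adjusted p 0.0094) had 1, Grm5, and immediate early genes (16, median -0.09, adjusted p 0.0132) had 0, with Egr4 standing at -0.22 without passing (adjusted p = 0.363 with an estimated correlation for both lists). Fry gave adjusted p from 0.171 to 0.184. Median and mean differed in sign for neuropeptides, endothelial, choroid plexus, glucocorticoid-responsive and heat shock genes, which did not pass.

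In limma 0 of 17265 probes passed (smallest adjusted p 0.310), and 2119 had an unadjusted p under 0.05 (1096 up, 1023 down; 863 by chance). Without the mouse as a block, as an interaction term over all arrays, the count was 1361. The alcohol effects in the fractions were nearly unrelated across 17265 probes, which are not independent replicates (Pearson r 0.04, Spearman rho -0.03). Joint relabellings of the mice gave a median r of 0.339, from -0.03 to 0.697, and 2 of 100, the real labels included, were as small. Of the probes with an unadjusted p under 0.05 in both fractions, 49 had the same direction and 32 the opposite. Independent calls would give 29.4 of the same direction, and the relabellings gave a median of 49 same-direction calls.

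**Figure D4:**
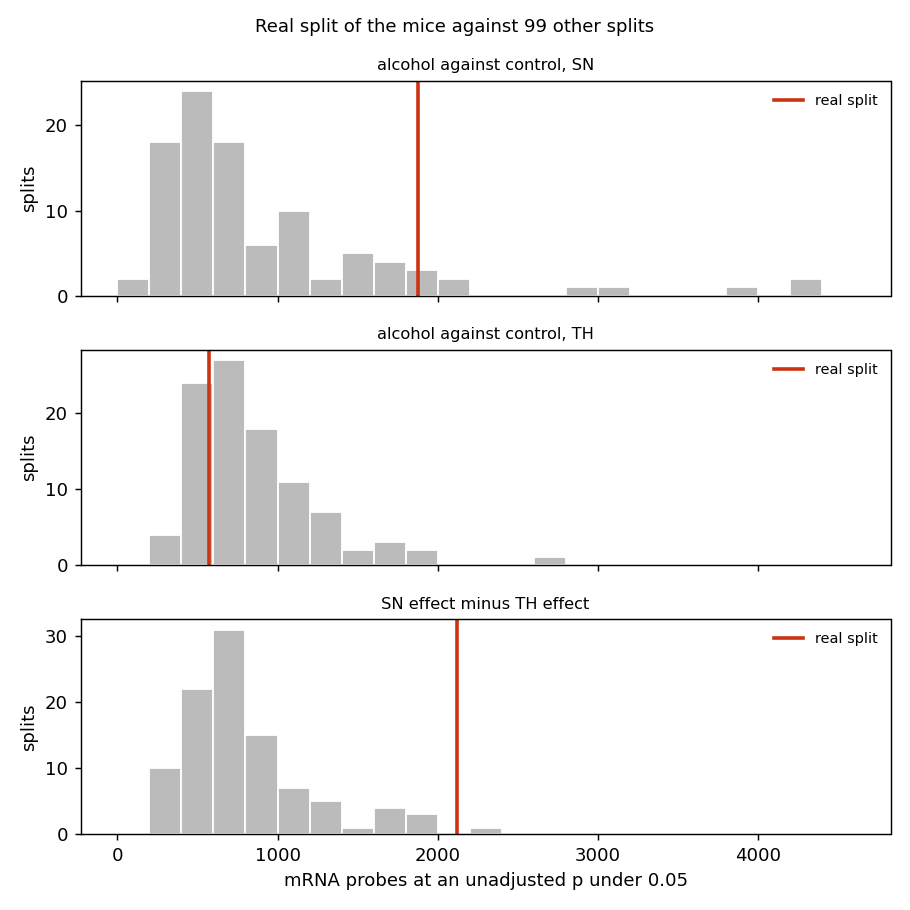
Histograms of the number of mRNA probes at an unadjusted p under 0.05 (x axis) over 99 other splits of the same mice (y axis, number of splits), for SN, TH and the SN minus TH difference, with the real split as a red line. The real counts were 1878, 571 and 2119, and the highest of the other splits 4372, 2776 and 2208.

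Alcohol and miRNAs were compared in 8 alcohol and 12 control mice. No miRNA passed in SN, where miR-466n-3p stood at 0.52 (SE 0.12), miR-875-3p at 0.69, miR-344c at -0.75 (SE 0.20) and miR-1187 at -0.79. The mean levels of miR-466n-3p and miR-875-3p were 0.97 and 1.11, close to the array medians of 0.82 to 1.00 and so to the floor of the array. Among miRNAs of earlier alcohol studies, miR-9 stood at 0.24, miR-206 at -0.54, miR-411 at -0.25 (SE 0.11), let-7b at 0.03 and the immune miR-155 at -0.02, and neuronal miR-137 and miR-124 at -0.61 and -0.04. With mean levels of 1.14 and 1.41, miR-206 and miR-155 lay near the floor too, so their values say little. In TH miR-3113-star stood at 0.53 (SE 0.12), miR-5100 at -0.74 (SE 0.18), miR-539-5p at -0.68 and miR-720 at -0.94. There miR-9 stood at -0.66 (SE 0.26), the choroid plexus miRNA miR-204 at -0.60 (SE 0.32), miR-206 at -0.46 (mean level 1.21, near the floor), miR-411 at -0.18 and let-7b at 0.15. The SN minus TH difference of the effects was 0.90 (SE 0.35) for miR-9, 1.10 for miR-5100, 1.05 for miR-875-3p (near the floor in SN), -0.76 for miR-1895 and -0.77 for let-7b-star. None of the 11 miRNA lists passed in SN, in TH or for the difference, with smallest adjusted p-values of 0.135, 0.188 and 0.340 in camera and 0 calls in fry; adjusted over the list alone, 0 members passed. Median and mean differed in sign for astrocyte and oligodendrocyte miRNAs in SN and for the difference, for the clusters of miR-17 and miR-15 in TH, and for miRNAs of earlier alcohol studies for the difference. After quantile normalization 1 list passed in TH, the families of miR-29 and miR-30 (median -0.12, adjusted p 0.0326; -0.08 and 0.276 without it).

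In limma 0 of 1111 miRNA probe sets passed in SN (smallest adjusted p 0.426), with 65 at an unadjusted p under 0.05 (23 up, 42 down; 55.6 by chance), or 37 up and 36 down after quantile normalization. In TH 0 passed (0.220), with 77 (39 up, 38 down), and for the difference 0 passed (0.371), with 86 (36 up, 50 down). An unmoderated test per probe gave 0 adjusted calls in both fractions, with 65 in SN and 77 in TH at an unadjusted p under 0.05. Without control 13, miR-3113-star passed in TH, at 0.58 (adjusted p 0.0489). Its mean level was 1.16, near the array medians of 0.82 to 1.00, so it lay close to the floor of the array.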

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

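Among the tests in this part, leaving out controls 12 and 13 and the random covariates beside the SN count were chosen only after the result was seen.

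In 8 gene lists the alcohol effect in SN differed from that in TH by camera at the preset correlation, by the median of the difference of effects: -0.10 for the postsynaptic density, -0.13 for presynaptic vesicle and release, -0.12 for glutamate receptors, -0.094 for immediate early genes, and 0.11, 0.11, 0.11 and 0.10 for microglia markers, ribosomal proteins, oxidative phosphorylation and ethanol metabolism. Each call was lost with an estimated one (adjusted p = 0.363 with an estimated correlation).

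More mRNA probes had an unadjusted p under 0.05 for alcohol in SN (1878) and for the SN minus TH difference (2119) than in TH (571). For the difference, 2 of 100 splits, the real one included, gave as many (highest other 2208), under the bound set beforehand. This share is the smallest of several such alcohol tests and was not adjusted for their number, so chance is made less likely but is not excluded. In SN 11 of 100 gave as many (highest other 4372) and in TH 75 of 100 (highest other 2776). Some splits lay so far above the real counts that they point to a structure of the samples. With the number of detected probes as a covariate the SN count was 851, within the bound of 856.5 set beforehand as 1.5 times the TH count, but 14 of 100 random covariates equally related to group gave as few, so this explanation stays open. For the difference, the covariate left 679 probes, under the 863 that chance gives, and 4 of 100 random covariates gave as few. The covariate is counted on the same arrays and was related to group (correlation -0.55), so it could also take up an effect of alcohol. The test therefore cannot decide between the 2, and no value here measures RNA yield or quality. Without controls 12 and 13 the SN count was 1157, while leaving out other pairs of controls gave 1135 to 3170 and 1 of 77 fewer, so that their part in it stays open too. An effect of alcohol at synapses, the biological explanation the design gives, stays open and untested, since the detected probes differ between the same groups.

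A single mouse stood far from the other 7 of its group in 4 of 70 sets of values tested, against 3.5 that chance gives. Each set held 1 gene, 1 miRNA or the number of detected probes in a group of 8 alcohol mice. Control groups were not tested in this way. Mbp was 14.02 in SN of alcohol mouse 5, against 14.6 to 15.2 in the others. Penk was 8.72 in TH of alcohol mouse 8, against 8.20 to 8.43. miR-206 was 1.81 in SN of alcohol mouse 2, against 0.40 to 0.94. miR-411 was 6.17 in TH of alcohol mouse 8, against 6.52 to 6.81.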

How the results depend on the processing

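Leaving out controls 12 and 13 and the scalings of the lists were chosen only after the results were seen. Counts for SN against TH stayed within 1.5 times under other settings, apart from leaving out single mice, at 4807 to 7555 for mRNA and 46 to 75 for miRNA. The 46 miRNA calls were those without controls 11 and 12, and 32.6% of them were rises. On quantile-normalized mRNA signals 6962 of 7306 calls were shared with the same direction. No named gene changed sign while passing at an adjusted p under 0.05 in either fit. For alcohol almost no probe passed in any fit, so that rule could hardly be met there. Other changes of sign, of named genes and lists together, numbered 1 to 37 per comparison over all settings, the most for alcohol in mRNA TH. The adjusted counts for alcohol stayed at 0 apart from 1 case below. Unadjusted counts moved among probes of above-median level alone, where fewer probes were tested: 1049 (mRNA SN), 260 (mRNA TH), 41 (miRNA SN), 47 (miRNA TH) and 53 (miRNA difference). They were 1157 in mRNA SN with controls 12 and 13 left out. Mice of equal number were also fitted as a block, with only the numbers present in both groups (8 per group for mRNA and 7 for miRNA). The counts were then 1331 in mRNA SN, 1060 in mRNA TH, 70 in miRNA SN and 72 in miRNA TH. Block and group size changed together in these fits. With no replicate block the counts were 6109 and 75 for SN against TH and 1361 for the mRNA difference. The cause was not tested in either case. Of the lists, 10 became 3 for SN against TH with an estimated correlation and 18 in fry; in SN 13 became 0 and 1, in TH 9 became 0 and 0, and for the difference 8 became 0 and 0. miRNA lists for SN against TH went from 0 to 5 in fry and 3 after quantile normalization, and in TH from 0 to 1 after quantile normalization; the cause was not tested. Leaving out 1 mouse gave 6360 to 7019 for mRNA SN against TH, 42 (without control 2; 43 without control 3) to 68 for miRNA, unadjusted counts of 1240 (without alcohol 7) to 2626 in mRNA SN and 443 to 734 in mRNA TH, 50 to 85 and 66 to 92 in miRNA SN and TH, and adjusted counts of 0 throughout for alcohol except miRNA TH, 0 to 1 (without control 13). A block for BeadChip could not be run without chip names, nor hairpins together with mature miRNAs (0 hairpin probe sets). Low signal over background limits the rest: the mRNA scale is compressed there, and 249 of 1111 miRNA probe sets had a mean over 4.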

Other observations

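The tests of astrocyte markers against the genes outside the astrocyte and endothelial lists and of Ttr against miR-204 were chosen only after the result was seen.

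Between SN and TH of the 11 control mice 39.5% of all probes passed, so a list may hold genes that passed by that share alone. Several lists did not pass camera, which compares a list with other genes, yet held genes that passed. Among them, oligodendrocyte precursor markers had a median above 0 in 11 of 11 pairs. Cholesterol biosynthesis had 10 rises and 2 falls of 20 (median 0.07, camera adjusted p 0.141), with Srebf2, its master transcription factor, at 0.31 and Ebp at -0.32. Translation factors had 10 rises and 4 falls of 30 (median 0.09, adjusted p 0.135), with the elongation factor Eef1d at 0.42 and the helicase Eif4a1 at -0.36. Among 15 genes of ethanol metabolism 4 rose and 3 fell (median 0.03, adjusted p 0.539), with the mitochondrial acetate-activating Acss1 at 0.78 (SE 0.04) and Aldh1a1 at 0.38. Glucocorticoid-responsive genes had 6 rises and 4 falls of 20 (median 0.06, adjusted p 0.157), with Glul, the astrocyte glutamine synthetase, at 0.39 and Pdk4 at 0.34. Innate immune genes had 3 rises and 7 falls of 22 (median -0.02, adjusted p 0.135), with the interferon-induced Ifitm3 at -0.95 and Irf1 at -0.29. Oligodendrocyte precursor markers had 4 rises and 1 fall of 9 (median 0.05, adjusted p 0.245), with Ptprz1 at 0.77 and Bmp4 at -0.16. Adjusted over the list alone, translation factors had 10 rises and 5 falls, glucocorticoid-responsive genes 7 and 4, and oligodendrocyte precursor markers 5 and 1; the other counts of these lists were as given.

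Lists of neurons of neighbouring regions did not pass camera either, and the counts below also stand against 39.5% of all probes. Striatal markers had 1 rise of 13, Gng7 at 0.57 (median -0.02, adjusted p 0.865), and cortical and hippocampal markers 1 rise and 4 falls of 16 (median -0.02, adjusted p 0.539), with Cux2 at 0.26 and Nrgn at -0.25. Thalamic and hypothalamic markers had 3 rises and 4 falls of 10 (median -0.15, adjusted p 0.551), with Tcf7l2 at 0.17 and the peptide gene Avp at -0.33. Immediate early genes had 2 rises and 3 falls of 16 (median -0.03, adjusted p 0.557), with Arc, whose mRNA travels to active synapses, at 0.34 and Dusp1 at -0.22. Ion channels and adenosine signalling had 3 rises and 1 fall of 17 (median -0.01, mean 0.05, adjusted p 0.847), with the adenosine receptor Adora1 at 0.41 and Glra2 at -0.29. Nuclear-retained noncoding RNAs had 1 rise and 2 falls of 9 (median -0.12, adjusted p 0.234), with Xist and Neat1 falling, the latter by 0.30. By pair, the median of this list was 0.24 in control 13 and from -0.53 to 0.11 in the other mice. Choroid plexus markers had 1 rise and 3 falls of 10 (median 0.00, mean -0.10, adjusted p 0.550), with Clic6 at 0.25 and Igf2 at -0.64. Adjusted over the list alone, immediate early genes had 1 rise and 1 fall, and the other counts of these lists were as given.

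Astrocyte markers were higher and endothelial markers lower in SN than in TH, in every pair of control mice. The authors' normalization is argued against as the cause of the gap between these lists. In signals not normalized between arrays the astrocyte median exceeded the endothelial by 1.51 in the median pair (1.19 to 1.94). A shift of a whole array cancels in this gap, so the test cannot decide on the sign of either list alone. A lower share of vessel RNA would raise all other transcripts alike. The astrocyte median exceeded that of the 12581 genes outside both lists by 0.46 in the median pair (0.38 to 0.62). This argues against it as the whole cause for astrocytes, but it restates the camera result on the same arrays and is no separate test. The lower endothelial markers stay open to a lower share of vessel RNA. Chance is made unlikely for the number of probes called, with 1 of 100 splits, the real one, giving 7045 (highest other 3199). The same share, 1 of 100, was found for the 69 miRNA calls (highest other 7). It is the smallest share these splits can give, and they count all calls and not these lists. It may be that the filters hold vessel pieces back and let astrocyte processes through, a hypothesis that no value here tests.

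Choroid plexus markers were lower in alcohol mice, by a mean of -0.38 in SN and -0.29 in TH, but Ttr spanned 8.39 to 14.7 over all SN arrays (78.1-fold) and 8.85 to 14.8 in TH. Unequal amounts of choroid plexus in the dissected pieces may account for that spread: with group means removed, Ttr and miR-204 in TH correlated across 18 mice (Pearson r 0.788, permutation p 0.00011, adjusted 0.000137; Spearman rho 0.742, permutation p 0.00067; r 0.688 without the 2 farthest mice; 5 relations tested). In SN the relation did not hold (r 0.283, permutation p 0.226; rho 0.414, permutation p 0.0714; r 0.091 without the 2 farthest mice), although Ttr correlated with the mean of the other choroid plexus markers in SN (r 0.779, permutation p 3e-05, adjusted 5e-05; rho 0.738, permutation p 0.00024; r 0.651 without the 2 farthest mice) and in TH (r 0.781, permutation p 3e-05, adjusted 5e-05; rho 0.700, permutation p 0.0012; r 0.654 without them), and Ttr in SN with Ttr in TH (r 0.908, rho 0.865, permutation p 1e-05 for both, the smallest these permutations can give, adjusted 5e-05; r 0.855 without them). Chance between the groups stays open, with exact permutation p of 0.0605 in SN and 0.157 in TH for the mean of the markers (0.0349 and 0.126 for Ttr alone, not adjusted). An effect of alcohol on the choroid plexus itself stays open and untested.

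For the miRNA alcohol comparisons chance could not be excluded either. Of 100 splits 16 gave as many as the 65 miRNA calls in SN (highest other 102), 6 as many as the 77 in TH (highest other 103) and 5 as many as the 86 for the difference (highest other 109).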
